A study of Gallus gallus with 4 samples.

How the data were processed

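RNA-seq was performed on cranial neural folds of chick embryos (Gallus gallus). These are the paired ridges of the head neural plate from which the cranial neural crest arises. Per the labels' protocols, eggs were incubated at 37 °C for about 18 h to Hamburger-Hamilton stage 4 (HH4, gastrula), and the embryos were electroporated with Cas9 and guide plasmids. They were then grown for about 14 h to an early stage 9 (HH9-). Per the series' design text, the plasmids with guides against Chiwi, the chicken PIWI protein PIWIL1, went to the right side of each embryo and the control guides to the left side. Tissue of several embryos was pooled per library. Group and side therefore coincide in every library. There were 2 knockout and 2 control libraries. The labels do not say how many embryos made up a pool, or whether the libraries that share a replicate number hold the right and left sides of the same embryos.

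Each library had a table of whole-number read counts per Ensembl gene ID and a table of whole-number read counts per repeat name, both deposited by the authors without a header. Per the submitters' processing notes, Bowtie2, featureCounts and DESeq2 were used with the galGal6 build. Their versions and settings, the strand setting and the treatment of reads that map to many places are not given in the sources used here. Reads from the many copies of a repeat, and from repeats that share sequence (such as ENS1-LTR and ENS1B-LTR), can be split or dropped depending on that treatment. Whether a read inside a gene that overlaps a repeat was counted in both tables is likewise not given in the sources used here. A repeat count may therefore hold reads from host transcripts.

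The gene tables list 24356 Ensembl IDs. The reference table used here pairs 0 of them with a symbol, so no gene is named, and the level of Chiwi and the gene lists fixed for neural crest, neural plate, other tissues and stress were not analysed here. The biology that follows therefore rests on the repeat tables, which carry names. Their 11336 names were sorted into 7 classes by name patterns written beforehand, and 54 names, 36 of them tested, matched no pattern. The class called DNA transposon also takes ancient conserved elements (names beginning with UCON or MER). RSV-int and GGXHOI are among the 54 names that stayed unclassed.

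Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Features were kept by filterByExpr (minimum count 10, minimum total 15), which left 15589 genes and 2803 repeat names. The quasi-likelihood test (glmQLFit and glmQLFTest, default settings) was fitted with the group as the only term. Library sizes and TMM factors came from the gene table for both tables, so repeat levels are given as CPM relative to the gene reads of the library, and a shift of all repeats would stay visible. P-values were adjusted by Benjamini-Hochberg within each table, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were the fold change divided by the square root of the F statistic. Intervals are 95% intervals from the same fit. Repeat classes with at least 3 tested names were compared with all other names by limma 3.58.1 (camera, preset correlation 0.01, prior count 2 on log2 CPM). Summed CPM per class was compared by an exact two-sided permutation test, whose smallest possible p with 2 against 2 libraries is 0.33.

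Features were named by a rule set before the data were examined. It takes ERNI (ENS-1) where listed, and any repeat named Soprano, which holds the ERNI sequence. Of the repeats it takes those past the threshold, filled to 3 per direction by the smallest unadjusted p. The conditions of no overlap between groups and a mean of at least 1 CPM were set for genes. They were applied to these repeats too. The choice of up to 4 names with the smallest p was set for gene lists and was extended to repeat classes. The rule did not spell out the 4 ENS repeat names, which were chosen to stand for ERNI. Adjustment over a list alone was planned for gene lists, not for these names. Exceptions are marked in the text. The comparison, the tests, the lists and the alternatives were also fixed before the data were examined, apart from the list of ENS repeat names and those marked as added. The alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios size factors, no low-count filter, a replicate block, robust=TRUE, scaling from the repeat table, removal of simple repeats, other class tests, and leaving out each library. A fit with legacy=FALSE was added after seeing the data, because the planned legacy=TRUE proved to be the default of the installed version. Camera with an estimated correlation in the fits that leave out a library, the LTR sum without the ENS names, and random draws of LTR names without each library, were also added after seeing the data.

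The method was tested on simulated counts drawn with the means, library sizes and common dispersion of these libraries. Of 50 genes changed 1.5-fold, 31 were called among 15415 genes tested, and 48 of 50 changed 2-fold. At 1.25-fold, 4 of 50 were called. Among 2725 repeat names, 26 of 50 were called at 1.5-fold, 45 of 50 at 2-fold and 4 of 50 at 1.25-fold. Of the features left unchanged, 6 genes and 5 repeat names were also called. The changed features were drawn only from those with a mean of at least 1 CPM, so recovery at lower levels was not tested. The simulated counts had the same dispersion for all features and no difference between replicate numbers, so fewer changes may be found in the real libraries. In a simulated 1.25-fold rise of the DNA transposon class, camera called that class (adjusted p = 4.28e-14) and 1 other class that had not been moved. Names were drawn independently there, so this does not show that camera would find such a shift among correlated names.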

Results

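The series asked how loss of Chiwi, an Argonaute-family protein that binds piRNAs and is known for silencing transposons in the germ line, changes RNA in the cranial neural folds of the chick embryo. Knockout tissue from the right side was compared with control-guide tissue from the left side, in 2 libraries each. The gene tables held 38783357 and 39386284 reads for knockout replicates 1 and 2, and 40352750 and 40092258 for control replicates 1 and 2. The repeat tables held 2707324, 2942281, 2833502 and 2847205 reads in the same order. The libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 17.9 between the knockout libraries and 18.7 between the control libraries, so no library was treated as one deposited again. This does not tell separate pools from repeat preparations of a pool. Each is a pool of embryos, and whether pools of a group came from separate sets of embryos is not stated, so p-values measure the spread between these pools only. The test also borrows this spread across features, with prior degrees of freedom of 6.56 for genes and 78.1 for repeats. The p-value and interval of a repeat name therefore rest mostly on the spread of other names, and less on its own.

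The retroelements that encode ERNI lay higher in the knockout libraries on average, by a margin smaller than the difference between the libraries of a group. ERNI (also ENS-1) is a protein of the early chick epiblast and neural plate, encoded by an endogenous retrovirus family, and known to hold back the neural gene SOX2. ENS1-LTR, the long terminal repeat of this family, stood at 796 ± 112 CPM in knockout and 642 ± 122 CPM in control tissue (SD, n = 2 each). That is a log2 fold change of 0.31 (SE 0.12, 95% interval 0.077 to 0.54), or 1.24-fold. ENS1-int, its internal part, stood at 764 ± 104 against 647 ± 87.6 CPM, a log2 fold change of 0.24 (SE 0.11, interval 0.011 to 0.47). ENS1B-LTR was at 190.0 ± 31.0 against 167 ± 39.0 CPM (log2 fold change 0.18, SE 0.12). The related ENS3-int was at 88.4 ± 15.2 against 80.0 ± 18.9 CPM (log2 fold change 0.14, SE 0.12).

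In the edgeR quasi-likelihood test, 0 of these 4 elements passed over all repeats tested, with an adjusted p of 0.9998 for ENS1-LTR. Adjusted over the list alone, 1 passed, ENS1-LTR, with an edgeR adjusted p of 0.039. ENS1-int had 0.080 and the others had 0.17 and 0.25. ERNI was put on the list from knowledge of the study, which may have chosen it on these samples, so this count is not independent evidence of its direction. Knockout and control libraries overlapped for all 4 elements. For ENS1-LTR, knockout replicate 2 had 716 CPM and control replicate 1 had 728 CPM. Between libraries with the same number, ENS1-LTR was higher in the knockout library by 0.27 log2 units for number 1 and by 0.37 for number 2. ENS1-int was higher by 0.24 in both. Without control replicate 2 or without knockout replicate 1, the count adjusted over the list alone was 0. It was 4 without control replicate 1 or without knockout replicate 2. It was also 0 with DESeq2 (smallest adjusted p = 0.14), without a low-count filter (edgeR adjusted p = 0.197) and without simple and low-complexity repeats (edgeR adjusted p = 0.151). It was 2 with limma-voom and with scaling from the repeat table.

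**Figure D1:**
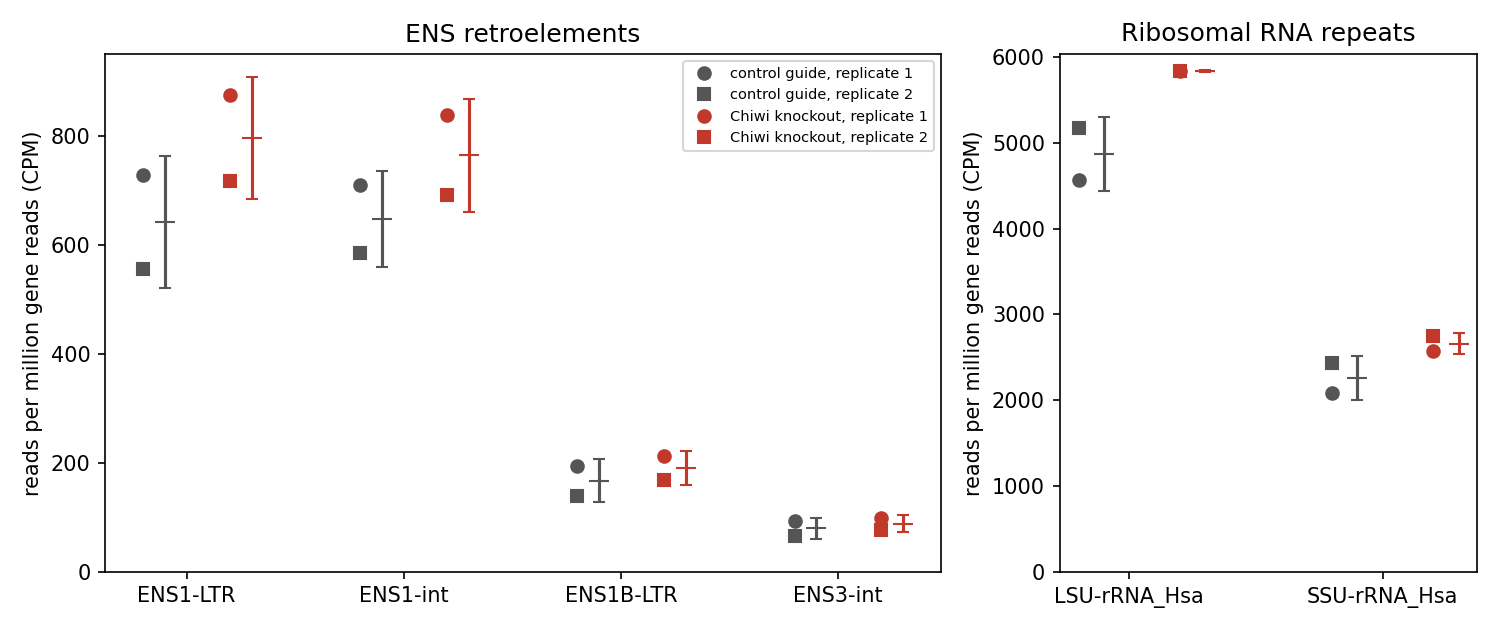
CPM relative to gene reads (linear axes from 0) of the 4 ENS retroelements (left) and the 2 ribosomal RNA repeat names (right) in each library, with points for libraries and bars for the mean ± SD of the 2 libraries of a group. For ENS1-LTR, knockout replicate 2 (716 CPM) lies below control replicate 1 (728 CPM), whereas both knockout libraries lie above both control libraries for LSU-rRNA_Hsa and SSU-rRNA_Hsa.

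Of the 58 other LTR names, those of endogenous retroviruses, 22 had a positive and 36 a negative log2 fold change. Over all 62 LTR names tested, the ENS names included, the median was -0.010. It was 0.019 without knockout replicate 1 and -0.058 without knockout replicate 2. Of the 62 names, 0 passed, over all repeats or adjusted over the list alone. GGLTR3B4, a chicken retroviral LTR, was at 6.46 ± 0.845 CPM in knockout and 8.42 ± 0.790 CPM in control tissue (log2 fold change -0.38, SE 0.17, edgeR adjusted p = 0.9998). RSV-int and EAVHP_I-int, the internal sequences of the Rous sarcoma virus and an endogenous avian retrovirus family, had log2 fold changes of -0.065 (SE 0.11) and -0.080 (SE 0.12). They were singled out after their values were seen. Summed over all LTR names, the ENS names included, the level was 4699 ± 121 CPM in knockout and 4430 ± 321 CPM in control tissue, a ratio of 1.06 (exact permutation p = 0.667, two-sided). Without the 4 ENS names it was 2860 ± 141 against 2894 ± 54.0 CPM, a ratio of 0.99 (exact permutation p = 1, two-sided). The class did not pass camera (adjusted p = 0.523).

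CR1 elements, the main LINE retrotransposons of birds, did not pass the test. Their summed level was 11290 ± 1102 CPM in knockout and 11580 ± 301 CPM in control tissue, a ratio of 0.975 (exact permutation p = 1, two-sided). Of 38 CR1 names, 32 had a negative log2 fold change, at a median of -0.040, and 0 passed the edgeR test. The 4 with the smallest p all lay lower: CR1-L3A_Croc had a log2 fold change of -0.14 (SE 0.11) and CR1-L3B_Croc of -0.11 (SE 0.11), while CR1-16_AMi had -0.21 (SE 0.21) and CR1-16_Crp -0.64 (SE 0.57). In camera the class had an adjusted p of 0.150. The names' direction was not shared by the pools: without knockout replicate 1 the median was 0.058, and without knockout replicate 2 it was -0.14, with a camera adjusted p of 0.023 at the preset correlation and an adjusted p of 0.712 with an estimated correlation.

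DNA transposons and ancient conserved elements summed to 867 ± 64.5 CPM in knockout and 896 ± 16.7 CPM in control tissue. Of 64 names, 41 had a negative log2 fold change, 0 passed, and the camera adjusted p was 0.150. UCON9B had -0.57 (SE 0.24), MER132 had -0.35 (SE 0.18), UCON26 had -0.31 (SE 0.17) and UCON17 had 1.13 (SE 0.66) at a mean of only 0.261 CPM. The UCON17 value was 0.37 without control replicate 1 and 2.79 without control replicate 2. Without knockout replicate 2 the class passed camera (median -0.12, adjusted p = 0.038), and without control replicate 1 it lay at the threshold (median -0.058, adjusted p = 0.0499), both at the preset correlation. With an estimated correlation the adjusted p was 0.712 and 0.798. Other LINEs and SINEs summed to 498 ± 16.7 CPM against 510 ± 14.4 CPM, with 0 of 13 names passing and a camera adjusted p of 0.426. Their names with the smallest p were X8_LINE (-0.41, SE 0.29), X9_LINE (-0.39, SE 0.47), L2-1_AMi (0.15, SE 0.19) and X1_LINE (0.24, SE 0.34). Sat-CR1_GG, the single name that the satellite pattern matched, had a log2 fold change of -0.026 (SE 0.23). GGXHOI, a W chromosome repeat singled out after its values were seen, matched no class pattern. Its log2 fold change was 0.40, and ranged from -0.42 to 0.92 when 1 library was left out. The 36 tested names outside the classes had a median of -0.056, with 10 positive and 26 negative. They were not tested as a class.

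**Figure D2:**
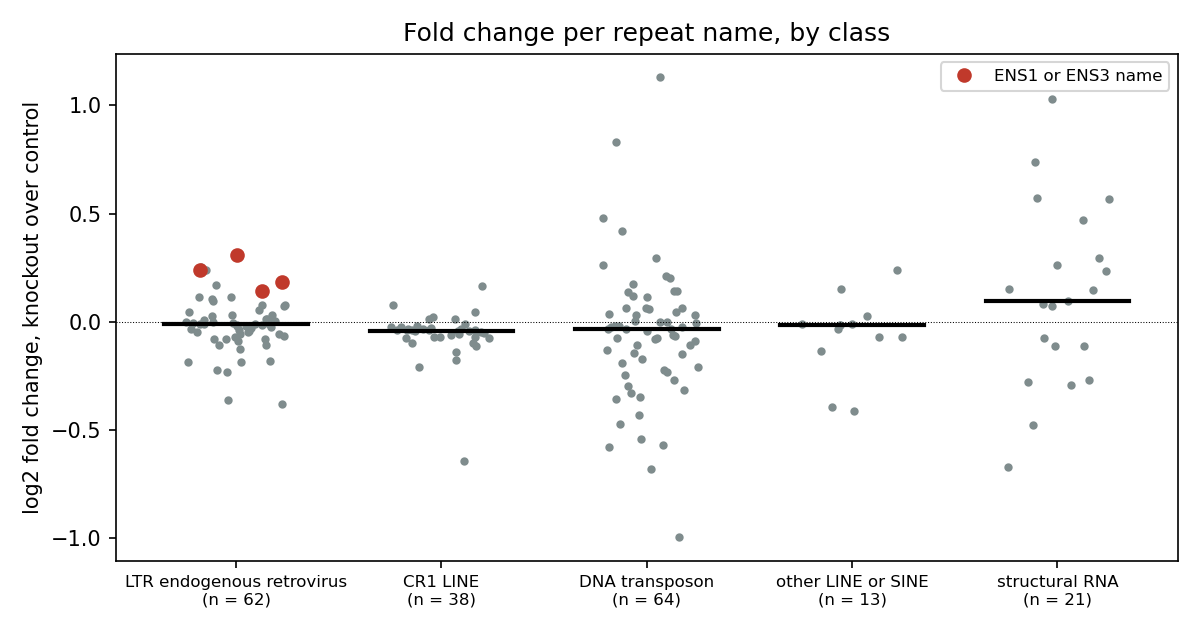
Log2 fold change of knockout over control (linear axis) for each tested name of the LTR, CR1, DNA transposon, other LINE or SINE and structural RNA classes. Simple and low-complexity, satellite and unclassed names are not shown. Each point is 1 name, red points are the 4 ENS names and black lines are class medians. The class medians lie between -0.040 (CR1) and 0.097 (structural RNA), and the 4 ENS names lie between 0.14 and 0.31.

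The ribosomal RNA names LSU-rRNA_Hsa and SSU-rRNA_Hsa, which dominate the structural RNA repeats, lay higher in both knockout libraries than in both control libraries. LSU-rRNA_Hsa, the large-subunit ribosomal RNA sequence, stood at 5837 ± 6.32 CPM in knockout and 4869 ± 429 CPM in control tissue (log2 fold change 0.26, SE 0.12). SSU-rRNA_Hsa, the small-subunit sequence, stood at 2660 ± 121 against 2261 ± 252 CPM (log2 fold change 0.23, SE 0.12). Neither passed the edgeR test (adjusted p = 0.9998 for both). Without control replicate 1 the log2 fold changes of LSU-rRNA_Hsa and SSU-rRNA_Hsa were 0.17 and 0.12, and without control replicate 2 both were 0.35. The arginine transfer RNA tRNA-Arg-AGA and the spliceosomal U1 had log2 fold changes of 0.74 (SE 0.40) and 0.47 (SE 0.29), at means of 0.664 and 1.44 CPM, and the groups overlapped for U1. The class sum was 8530 ± 135 CPM in knockout and 7162 ± 686 CPM in control tissue, a ratio of 1.19. The exact two-sided permutation p was 0.33, the smallest that 2 against 2 libraries can give. Of 21 names, 13 had a positive and 8 a negative log2 fold change, 0 passed, and the camera adjusted p was 0.267. The median over names, 0.097, turned to -0.28 without knockout replicate 2, and the class passed camera at the preset correlation without control replicate 2 (median 0.31, adjusted p = 0.015). With an estimated correlation the adjusted p without that library was 0.96.

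Simple and low-complexity repeats took 63.2% of all repeat reads and summed to 45370 ± 2490 CPM in knockout and 44950 ± 1180 CPM in control tissue. Of 2568 names tested, 0 passed. They make up most of the 2803 repeat names tested, and camera compares a class with all other names. The camera test of this class therefore largely mirrors those of the other classes. It placed the class above the other names with all libraries (median 0.002). It did so without knockout replicate 2 as well, where the median itself was -0.042. The camera adjusted p was 0.150, and it was 0.023 without knockout replicate 2 and 0.0499 without control replicate 1, at the preset correlation. With an estimated correlation the adjusted p was 0.712 and 0.798. The names with no overlap between groups and the smallest p had means of 1.82 to 18.0 CPM over the 4 libraries. (CACTGT)n was at 16.2 ± 1.48 CPM in knockout against 12.1 ± 0.717 CPM in control tissue, and (GCTCCGC)n at 3.87 ± 0.460 against 2.60 ± 0.260 CPM. (GCCCTCCT)n was at 2.91 ± 0.472 against 1.95 ± 0.129 CPM. In the other direction, (CGGCTCC)n was at 1.88 ± 0.212 against 3.11 ± 0.271 CPM and (CCCCGCC)n at 1.41 ± 0.154 against 2.23 ± 0.705 CPM. (CCCCTT)n was at 15.9 ± 2.39 against 20.1 ± 0.986 CPM, and (CCCGCGCT)n, under the minimum level for the ranking, at 0.153 ± 0.0714 against 0.608 ± 0.184 CPM. With an estimated correlation and all 4 libraries, no class passed camera (adjusted p = 0.799 for each).

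Across all repeats, 0 of 2803 names passed in the edgeR test and 45 had an unadjusted p under 0.05, where an even spread of p-values would give 140. DESeq2 and limma-voom also called 0. Of the names, 25.9% had no overlap between groups, against a chance share of 33.3%. The median 95% interval of a log2 fold change extended 0.50 to either side. Of the 32 repeat names given here for knockout against control, 25 had a log2 fold change that turned or moved by over 1.5 times when 1 of the libraries was left out.

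Across genes, 0 of 15589 passed in the edgeR test (smallest adjusted p = 0.9995), and 174 had an unadjusted p under 0.05, of which 62 were higher and 112 lower in knockout tissue. If p-values were spread evenly, 779 genes would lie under 0.05. limma-voom called 0 and DESeq2 called 1. The median absolute log2 fold change was 0.086, and 24.6% of genes had no overlap between groups, against the same chance share of 33.3%. This share holds for libraries that differ at random within a group, and the fit had no term for the replicate number, by which the libraries also differed. That difference counted as spread within a group, so the 0 calls do not show that no gene changed. The tables give Ensembl IDs only. The IDs below are at most 2 per direction, those with the smallest p among IDs with no overlap and a mean of at least 1 CPM, a choice made after their values were seen. ENSGALG00000002671, the DESeq2 call (adjusted p = 0.0146), was at 55.4 ± 3.24 CPM in knockout and 82.2 ± 3.09 CPM in control tissue, a log2 fold change of -0.57 (SE 0.090, interval -0.78 to -0.36). It passed edgeR without knockout replicate 2, control replicate 1 or control replicate 2 (adjusted p = 0.049, 0.014 and 0.0090). ENSGALG00000002645 was at 12.7 ± 0.247 against 19.8 ± 0.345 CPM (log2 fold change -0.64, SE 0.13). In the other direction, ENSGALG00000039572 was at 11.6 ± 0.467 against 7.78 ± 1.01 CPM (log2 fold change 0.57, SE 0.16) and ENSGALG00000003814 at 35.3 ± 0.450 against 27.6 ± 1.88 CPM (log2 fold change 0.36, SE 0.10). The edgeR count of genes was 63 without control replicate 1, and 2, 3 and 6 without knockout replicate 1, knockout replicate 2 and control replicate 2. Right and left sides coincide with knockout and control, and electroporation leaves untransfected cells in the tissue, so the values hold for the whole dissected fold.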

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

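All alternatives were planned except legacy=FALSE and those marked as added. The call of 0 genes and 0 repeats was kept under limma-voom, median-of-ratios size factors, no low-count filter, robust=TRUE, legacy=FALSE and a threshold of 0.10. DESeq2 called 1 gene and 0 repeats. Leaving out 1 library gave 2 to 63 genes and 1 to 2 repeats, in fits with a lone library in one arm that is assumed to vary like the others. The highest gene count came without control replicate 1. The repeats called were GGXHOI, (CTTGGC)n, ENS1-LTR and (CCGAGG)n, of which ENS1-LTR was called without control replicate 1 alone. With a replicate block, edgeR called 28 genes (4 higher, 24 lower) and 0 repeats. The 28 include the 4 IDs named in the report, with adjusted p of 8.37e-10 for ENSGALG00000002671, 6.95e-05 for ENSGALG00000002645, 0.0263 for ENSGALG00000039572 and 0.0401 for ENSGALG00000003814. In the block fit the prior degrees of freedom for genes were infinite, so each gene took a spread pooled over genes and none of its own. These p-values may therefore be too small. The labels do not say that a number marks the same embryos. The check made on this was 1 correlation of same-numbered deviations, 0.341 over genes and 0.167 over repeats, which 2 pools per group leave undecided. Of the 28 genes, 22 had no overlap between groups and 6 moved in opposite directions for the 2 numbers. The block left 1 ENS element past 0.05 adjusted over the list alone, and left every class on its side of the threshold.

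The number of ENS elements past 0.05, adjusted over the list alone, was 1 in the reported fit. It was 0 with DESeq2, without a low-count filter, and without simple and low complexity repeats, and 2 with limma-voom and with scaling from the repeat table. It ranged from 0 to 4 when 1 library was left out. The cause was not tested. ENS1-LTR kept its sign in all 13 alternatives, at 0.13 to 0.52, and so did ENS1-int, at 0.094 to 0.38. ENS1B-LTR ranged from -0.037 to 0.44 and turned without control replicate 2. ENS3-int ranged from -0.079 to 0.41, turned there, and was -0.043 without knockout replicate 1.

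Class tests changed direction or passed only when 1 library was left out, and passed there only at the preset correlation. With an estimated correlation, a setting added after seeing the data for these fits, 0 classes passed. Class medians then ranged from -0.14 to 0.058 for CR1, -0.12 to 0.034 for DNA transposons, -0.042 to 0.053 for simple repeats, -0.058 to 0.019 for LTR names, -0.076 to 0.012 for other LINEs and SINEs, and -0.28 to 0.31 for structural RNA. Structural RNA, at 0.012 without control replicate 1, also turned in camera there. The added LTR classes, without the ENS names or with RSV-int, did not pass. Single names that turned when 1 library was left out ranged from -0.58 to 0.084 (CR1-16_AMi), -0.24 to 0.16 (Sat-CR1_GG), -0.17 to 0.029 (RSV-int), -0.26 to 0.13 (EAVHP_I-int), -0.040 to 0.47 (X1_LINE), -0.77 to 0.057 (X9_LINE) and -0.42 to 0.92 (GGXHOI). The ratio of LTR sums, 1.06, was 0.99 in the added sum without the ENS names. Ratios of class sums that turned ranged from 0.906 to 1.04 (CR1), 0.916 to 1.02 (DNA transposons), 0.953 to 1.001 (other LINEs and SINEs) and 0.969 to 1.05 (simple repeats). The Chiwi level and the gene lists were not run, because no ID was paired with a symbol. Depth limits single names with few reads, such as (CCCGCGCT)n at 0.381 CPM.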

Other observations

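The tests in this part were chosen after the values were seen. The libraries with number 2 differed from those with number 1 in far more features than knockout differed from control. With the group as a term, edgeR called 777 genes higher and 839 lower in number 2 (adjusted p under 0.05), and 23 repeat names higher and 10 lower. These counts come from the replicate-block fit, in which a gene took a pooled spread in place of its own, so they may be too high. The first principal component of log2 CPM over genes, with 52.4% of the variance, separated the numbers. A-rich low-complexity sequence stood at 5072 and 4972 CPM in number 2 and at 3520 and 3371 CPM in number 1, for knockout and control (log2 difference 0.54, SE 0.12, edgeR adjusted p = 0.0032). The simple repeat (CTTGGC)n was at 6.96 and 7.03 CPM in number 2 against 0.900 and 1.03 CPM in number 1. The small nuclear and nucleolar RNAs U6 and U3 were higher in number 2, by 0.65 (SE 0.17) and 1.05 (SE 0.27) log2 units. ENS1B-LTR and ENS3-int were lower in number 2, by -0.41 (SE 0.11) and -0.42 (SE 0.11), with adjusted p of 0.022 and 0.020. ENS1-LTR, at -0.34 (SE 0.11), did not pass (edgeR adjusted p = 0.12), nor did ENS1-int, at -0.28 (SE 0.11, adjusted p = 0.37).

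The 4 ENS elements had positive fold changes together, at a median of 0.211. Among 10000 random draws of 4 of the other 58 LTR names, the middle 95% of medians ran from -0.133 to 0.067. The ENS median was 0.050 without knockout replicate 1 and 0.036 without control replicate 2, both inside the range of draws from the same fit (-0.119 to 0.123 and -0.179 to 0.091). Without knockout replicate 2 and without control replicate 1 it was 0.354 and 0.424, outside the range. The other 58 LTR names had a median of -0.012 with all libraries, and of -0.072 to 0.019 when 1 library was left out. They argue against a shift of all LTR elements as large as the ENS median with all libraries. Without knockout replicate 1 or control replicate 2 the draws cannot decide, because the ENS median itself was near that of the other names. The ENS names share sequence and copies, so they are not 4 independent draws. Within each number the knockout library was higher for all 4 elements, by 0.086 to 0.37 log2 units. Derepression after loss of Chiwi and a right-left difference may each account for the direction, and cannot be told apart here, because side and group coincide. Variation between single pools also stays open, with only 2 pools per group.

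Control replicate 2 held 23 genes at more than 2-fold above each of the other libraries, among 13313 genes with a mean of at least 1 CPM. Knockout replicate 1, knockout replicate 2 and control replicate 1 held 0, 1 and 0 such genes. In the downward direction, 8, 0, 9 and 5 genes lay more than 2-fold below each of the other libraries in knockout replicates 1 and 2 and control replicates 1 and 2. The 23 genes had a median count of 227 in that library. Of the 24 genes lower in knockout tissue under the replicate block, 6 were of this kind. A candidate explanation is RNA of a neighbouring tissue in that dissection, which the tables cannot decide, since 0 of the IDs are paired with a symbol. A biological difference between these embryos was not tested.

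GGXHOI, a repeat described from the female-specific W chromosome, was singled out after its values were seen. It was at 37.7 CPM in knockout replicate 2 and 23.0 CPM in control replicate 2, and at 14.9 and 16.9 CPM in knockout and control replicates 1.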
